A study of Homo sapiens with 12 samples.

How the data were processed

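RNA sequencing was done on 12 libraries of TC-71, a human Ewing sarcoma cell line, in 4 groups of 3: cells given DMSO, cells given the small molecule YK-4-279, cells transfected with a scrambled control and cells transfected against DHX9 (siDHX9). Per the labels' protocols, the drug and its DMSO control were applied for 16 hours, the dose was 2 mM as labelled, and transfected cells were collected at 48 hours. The labels' protocols name siRNAs while the series' design text names shRNAs, and the sequences are not given in the sources used here. The labels state 3 biological replicates per group, and each group is 1 cell line, so the spread between libraries is that of cultures.

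The deposited table holds 1 signal value per gene and library, which per the file headers is a count normalised with DESeq size factors. Per the submitters' processing notes, the tools named are FastQC, Picard, SAMtools, STAR 2.4.0 and DESeq, with the hg19 build. Those notes give no order or settings. The table has 78885 entries, of which 25787 carry a gene symbol and 43345 are at 0 in all 12 libraries. Symbols, identifiers and coordinates were taken from the table itself, where DHX9 shares 1 entry with its neighbour NPL. Whether reads were counted by strand is not given in the sources used here. Of 124 genes listed for the text, 24 overlap another expressed named gene, and their values are uncertain to the extent that the counting shared reads between them.

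Dividing each column by its smallest step gave whole reads within 0.1 for 100% of values in every library, for totals of 38.6 to 65.5 in units of 1e6 reads. The recovered reads were used for depth, for edgeR and for DESeq2. The depth of these libraries bounds counting error only, since reads without molecular identifiers are not independent molecules. Every pair of replicates differed by more than counting error.

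Named genes with a mean of at least 10 over the 12 libraries were kept, which left 14225 genes, 591 of them entries that name more than 1 gene. A further 3172 entries without a symbol passed the same minimum, held 3.91 to 4.9% of reads and were left out of the tests. The values were taken to log2 after adding 1 and fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group over all 12 libraries, a mean-variance trend and 8 residual degrees of freedom. All adjusted p values of genes are two-sided limma values with Benjamini-Hochberg adjustment over the 14225 genes, and a gene was called changed at an adjusted p under 0.05. The comparisons were YK-4-279 minus DMSO, siDHX9 minus scrambled, and the difference of these 2 effects. Genes called in both were counted against the number expected from independent lists, with Fisher's exact test. The DHX9 level also had an exact permutation test of 3 against 3 values, which cannot go below 0.1.

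There were 38 gene lists, of which 36 had at least 4 measured members. These were tested with limma's camera at a preset correlation of 0.01, two-sided, and adjusted over the lists of each comparison. The same test with the correlation estimated from the data, and fry, were run as alternatives. No kept entry carried a symbol from the list of mitochondrially encoded genes, although entries on the mitochondrial chromosome took 2.21 to 3.11% of reads. The levels of those genes were therefore not examined by list. Of the nuclear-retained long noncoding RNAs 3 were measured, 1 of them lower in each of the YK-4-279 and DHX9 comparisons. Both of these lists were left untested.

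The comparisons, the tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule took, for each comparison, the 10 genes with the largest rise and the 10 with the largest fall among called protein-coding genes with a mean of at least 100 in the higher group and no overlap between treated and control libraries. It also took the 5 genes each way with the largest changes shared by both comparisons, up to 4 members of each called list and up to 2 of the others, and 7 genes in any case. Biotypes came from the RefSeq gene table through symbols and synonyms, which gave a biotype for 98.2% of symbols. For the difference, where 4 groups enter, the rule was read as the 5 largest each way with an adjusted p under 0.05 and a mean of at least 100 in the highest group, with no requirement on overlap.

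Alternatives were added values of 0.5 and 10 before the logarithm, no minimum and a minimum mean of 50, TMM factors (edgeR 4.0.16) on the deposited values, quantile normalisation, only the 6 libraries of a comparison, robust moderation, no mean-variance trend, edgeR's quasi-likelihood test, DESeq2 1.42.0, the replicate number as a block, each library left out in turn, and a log2 fold change of at least 1. After the data were seen, fits with the unnamed entries, with limma's array weights and without both scrambled replicates 1 and 2 were added. The array weights ended with a warning that the convergence tolerance was not reached.

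The pipeline was tested on simulated data with 200 changed genes. For YK-4-279, over 14229 genes, limma called 43% of genes changed 1.5-fold and 79% of genes changed 2-fold, with a false share of 5.43%. For DHX9 knockdown, over 14226 genes, it called 40% and 78% of them, with a false share of 6.35%. DESeq2 gave false shares of 15.9% and 18.7% in the same order. The simulation gave each gene the same dispersion in all groups. In the data, replicates differed more in the siRNA arm (chi-square of counts per degree of freedom 29.2 to 91.4) than in the drug arm (6.87 to 24.1). The simulated shares do not cover this unequal spread, so they do not give the false share of the real DHX9 calls.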

Results

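The data are RNA sequencing of TC-71, an Ewing sarcoma cell line that carries the EWS-FLI1 fusion, in 12 libraries. YK-4-279 is a small molecule developed to block the binding of EWS-FLI1 to DHX9, an RNA helicase. The design compares this drug with lowered DHX9, each against its own control. Total reads per library, in units of 1e6, were 38.6 to 65.5 in DMSO, 48.3 to 53.7 with YK-4-279, 47.8 to 51 in scrambled and 46.9 to 49.4 in siDHX9 libraries. Levels below are normalised read counts as mean ± SD with n = 3 per group, changes are fold changes or log2 fold changes with their SE, and coordinates are hg19. For every gene said to have risen or fallen, all 3 treated libraries lay on that side of all 3 controls, which chance alone gives for 10% of unchanged genes.

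DHX9 was lower in siDHX9 than in scrambled libraries, which checks the label of the transfected groups. The entry that joins DHX9 with NPL (chromosome 1, 182758584 to 182857117) held 20608 ± 1100 normalised counts in siDHX9 and 32689 ± 2130 in scrambled libraries (SD, n = 3), a level 37% lower (log2 −0.66 ± 0.07 SE, adjusted p = 4.54e-05). The exact permutation test gave p = 0.1, the smallest it can give. With YK-4-279 the entry held 29997 ± 597 against 34724 ± 1600 in DMSO (log2 −0.21 ± 0.07 SE), lower in 3 of 3 libraries at an adjusted p of 0.0567, just over the threshold. That adjusted p was 0.0038 when only the 6 libraries of the comparison were fitted. It was also under 0.05 with TMM, quantile normalisation, edgeR, DESeq2 and array weights. In 9 of 12 fits without 1 library it stayed over the threshold.

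**Figure D1:**
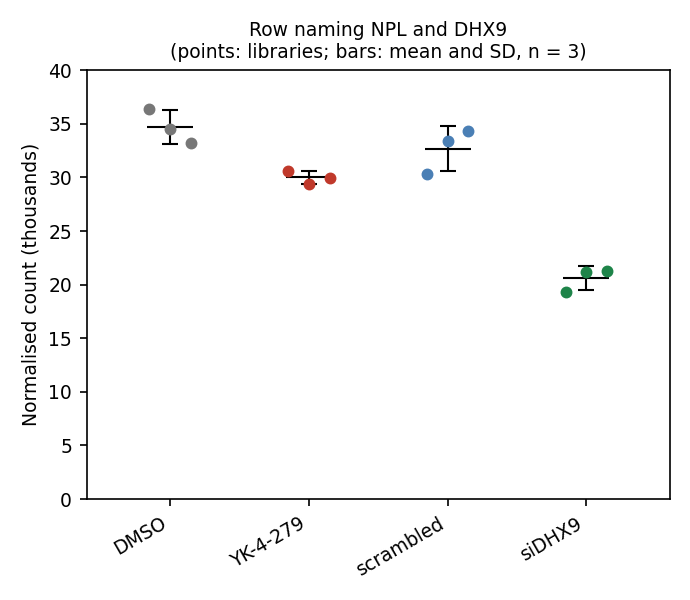
Normalised read count, in units of 1e3, of the entry that names NPL and DHX9 in each of the 4 groups. Points are libraries and bars are mean and SD (n = 3); the 3 siDHX9 libraries sit between 19342 and 21304, below all other libraries.

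The first comparison asked what YK-4-279 changed in these cells. In lists of 32 G1/S and replication genes and 23 repair genes 23 and 19 fell (adjusted p = 0.0736 for each with an estimated correlation), in a list of 28 mitosis genes 16 fell and 4 rose, and in a list of 20 immediate early genes 9 rose and 1 fell. CDK1, the kinase that drives entry into mitosis (GSHG0003392, chromosome 10), fell 3.86-fold, from 5248 ± 199 to 1360 ± 75.1 normalised counts (SD, n = 3, adjusted p = 1.41e-08). EGR1, a transcription factor induced by growth signals (GSHG0024271, chromosome 5), rose 7.84-fold, from 149.9 ± 22.3 to 1178 ± 115 (adjusted p = 1.89e-05). FOS, a part of activator protein 1, rose 6.16-fold to 3628 ± 277, and the related FOSB rose 12-fold to 532.2 ± 54.1, although FOSB overlaps ERCC1, at a mean of 4079.

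Homologous recombination and Fanconi anaemia genes, which repair DNA breaks and crosslinks, fell in 19 of 23 measured members, or 21 adjusted over the list alone. The list had a mean log2 change of −0.65 and a camera adjusted p of 5.11e-20, with an adjusted p = 0.0736 with an estimated correlation. BLM, a helicase of recombination, fell 1.83-fold to 1464 ± 67.5, and the nuclease EXO1 fell 1.78-fold to 2156 ± 88.7. FANCI fell 1.97-fold to 2792 ± 118 and overlaps POLG.

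Genes of the G1/S transition and DNA replication fell in 23 of 32 measured members, or 25 adjusted over the list alone (mean log2 −0.45, camera adjusted p = 2.7e-19, adjusted p = 0.0736 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell 1.66-fold to 23840 ± 471. CDC45 and GINS1, parts of the replicative helicase, fell 1.81-fold and 1.91-fold, and CHAF1B, a histone chaperone, fell 1.66-fold. In the list of G2/M and mitosis genes, 16 of 28 fell and 4 rose, or 16 and 7 adjusted over the list alone (mean log2 −0.41, camera adjusted p = 9.94e-07). UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell 2.88-fold to 5801 ± 422. The proliferation marker MKI67 fell 1.68-fold and NUSAP1, a spindle protein, 1.83-fold.

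Immediate early genes, the first to answer growth and stress signals, rose in 9 of 20 measured members and fell in 1, or 14 and 1 adjusted over the list alone (mean log2 0.93, camera adjusted p = 6.46e-08). IER2 rose 1.75-fold to 6876 ± 281. Targets of actin, SRF and YAP signalling rose in 9 of 18 members, or 12 adjusted over the list alone (mean log2 0.53, camera adjusted p = 1.44e-06, adjusted p = 0.131 with an estimated correlation). SRF, the transcription factor of serum response, rose 1.83-fold to 1175 ± 85.1. Zyxin (ZYX), a focal adhesion protein, rose 1.83-fold, CYR61, a secreted matrix protein, rose 2.07-fold, and ACTG1, a cytoplasmic actin, rose 1.42-fold.

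Genes that EWS-FLI1 represses rose in 7 of 21 measured members, with 7 adjusted over the list alone (mean log2 0.43, camera adjusted p = 0.00212, adjusted p = 0.222 with an estimated correlation). Among them the stress-induced IER3 rose 2.03-fold and overlaps TUBB, which fell 1.42-fold. The list of repressed genes shares CYR61, CTGF, TAGLN and ZYX with the list of actin, SRF and YAP targets. The rises of CYR61 and ZYX therefore count in both lists, which are not separate results. Of 33 measured genes that EWS-FLI1 activates, 2 rose and 4 fell, or 3 and 4 adjusted over the list alone (mean log2 −0.03, camera adjusted p = 0.325). EZH2, a histone methyltransferase, fell 1.28-fold and the kinase VRK1 fell 1.37-fold, while CCND1, cyclin D, rose 1.38-fold and overlaps ORAOV1. NR0B1, a nuclear receptor that is a classic target of the fusion, was at 6559 ± 456 against 6914 ± 188 in DMSO (adjusted p = 0.508). EWSR1 (log2 0.11 ± 0.08), FLI1 (0.23 ± 0.22), MYC (0.19 ± 0.08) and CDKN1A (0.14 ± 0.17) did not pass the test, and the FLI1 entry was low, at 136.2 ± 14.6, with fusion reads not told apart from those of its partner genes.

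Autophagy and lysosome genes rose in 6 of 17 members, or 9 adjusted over the list alone (mean log2 0.29, camera adjusted p = 0.000174, adjusted p = 0.247 with an estimated correlation). LAMP1, a lysosomal membrane protein, rose 1.4-fold to 15180 ± 574, and MAP1LC3B, which coats autophagosomes, rose 1.29-fold. Host genes of small nucleolar RNAs fell in 4 of 11 members, with 4 adjusted over the list alone (mean log2 −0.27, camera adjusted p = 0.000463, adjusted p = 0.324 with an estimated correlation). SNHG12 fell 2.11-fold to 2329 ± 122 and SNHG1 fell 1.41-fold, both in stretches that overlap other genes. Of 7 measured histone genes 3 rose and 1 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.133). HIST1H2BD rose 3.47-fold and HIST1H2BK 2.48-fold, values that are uncertain because histone genes have near-identical copies. The tubulins TUBB and TUBA1C fell 1.42-fold and 1.69-fold in a list of 11 in which 2 rose and 2 fell, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.329). The entry for ribosomal RNA took 8.79% ± 1.07 of reads with YK-4-279 and 5.19% ± 0.245 in DMSO (SD, n = 3), beside all of these groups.

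A pair of lists passed the test more weakly. Extracellular matrix genes rose in 3 of 21, or rose in 6 and fell in 1 adjusted over the list alone (mean log2 0.23, camera adjusted p = 0.0465, adjusted p = 0.519 with an estimated correlation), with COL6A1, a collagen VI chain, up 1.58-fold. Their adjusted p was 0.0518 to 0.0875 without DMSO replicates 2 or 3, YK-4-279 replicates 1 or 2, or siDHX9 replicates 2 or 3, each left out alone, and the call was also lost with an added value of 10, with no minimum or a minimum mean of 50, on the 6 libraries alone, in edgeR and DESeq2, with the replicate block and with array weights. Ribosomal protein genes had a mean log2 change of 0.11 (camera adjusted p = 0.0194, adjusted p = 0.677 with an estimated correlation), with 0 of 33 called by limma, also adjusted over the list alone, against 3 at an unadjusted p under 0.05 and 0 by edgeR or DESeq2. That list's adjusted p was 0.0527 to 0.231 without DMSO replicate 1, YK-4-279 replicate 2 or YK-4-279 replicate 3, and the call was also lost with no minimum, under quantile normalisation, in edgeR and DESeq2 and by fry.

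The other genes with the largest falls were TOP2A (3.6-fold), a topoisomerase of mitotic chromosomes that overlaps RARA, E2F8 (3.17-fold), a repressor of the cell cycle, FBXO5 (2.51-fold), an inhibitor of the anaphase-promoting complex, ARHGAP33 (3.25-fold), MTFR2 (2.76-fold), C21orf58 (2.46-fold) and SPIN4 (2.41-fold). GOLGA8H fell 2.97-fold and belongs to a family of near-identical copies, so its value is uncertain. Among the largest rises were PYGM (3.93-fold), the muscle glycogen phosphorylase, CHRNB2 (3.24-fold), a nicotinic receptor subunit, PIK3IP1 (2.58-fold), an inhibitor of PI3-kinase signalling, and SERINC2 (2.44-fold). SERINC2 had an adjusted p of 0.0626 to 0.107 without any 1 of DMSO replicates 1 and 2 and YK-4-279 replicates 1, 2 and 3. The entry of the near-identical copies HIST2H2AA3 and HIST2H2AA4 rose to 744.8 ± 82.5 from 85.05 ± 147, a control mean that rests on DMSO replicate 1, and DESeq2 did not call it.

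Across the 14225 genes, 1042 were higher and 923 lower with YK-4-279, 1965 in all (926 higher and 1072 lower with TMM, 939 and 1059 in edgeR, 1065 and 1190 with unnamed entries included), of which 205 changed by a log2 fold change of at least 1. Of the 36 lists tested 10 were called, and those of immediate early genes (adjusted p = 0.00779) and of G2/M and mitosis (adjusted p = 0.0422) were also called with an estimated correlation. The other 26 had camera adjusted p values of 0.133 to 0.941. Median, mean and test differed in sign for interferon-stimulated genes (median −0.04, mean 0.07, test higher), ribosome biogenesis (−0.01, 0.05, higher) and RNA helicases other than DHX9 (−0.09, 0.02, lower). The count was 4270 when only the 6 libraries of the comparison were fitted, and 858 to 1151 without any 1 of them.

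**Figure D2:**
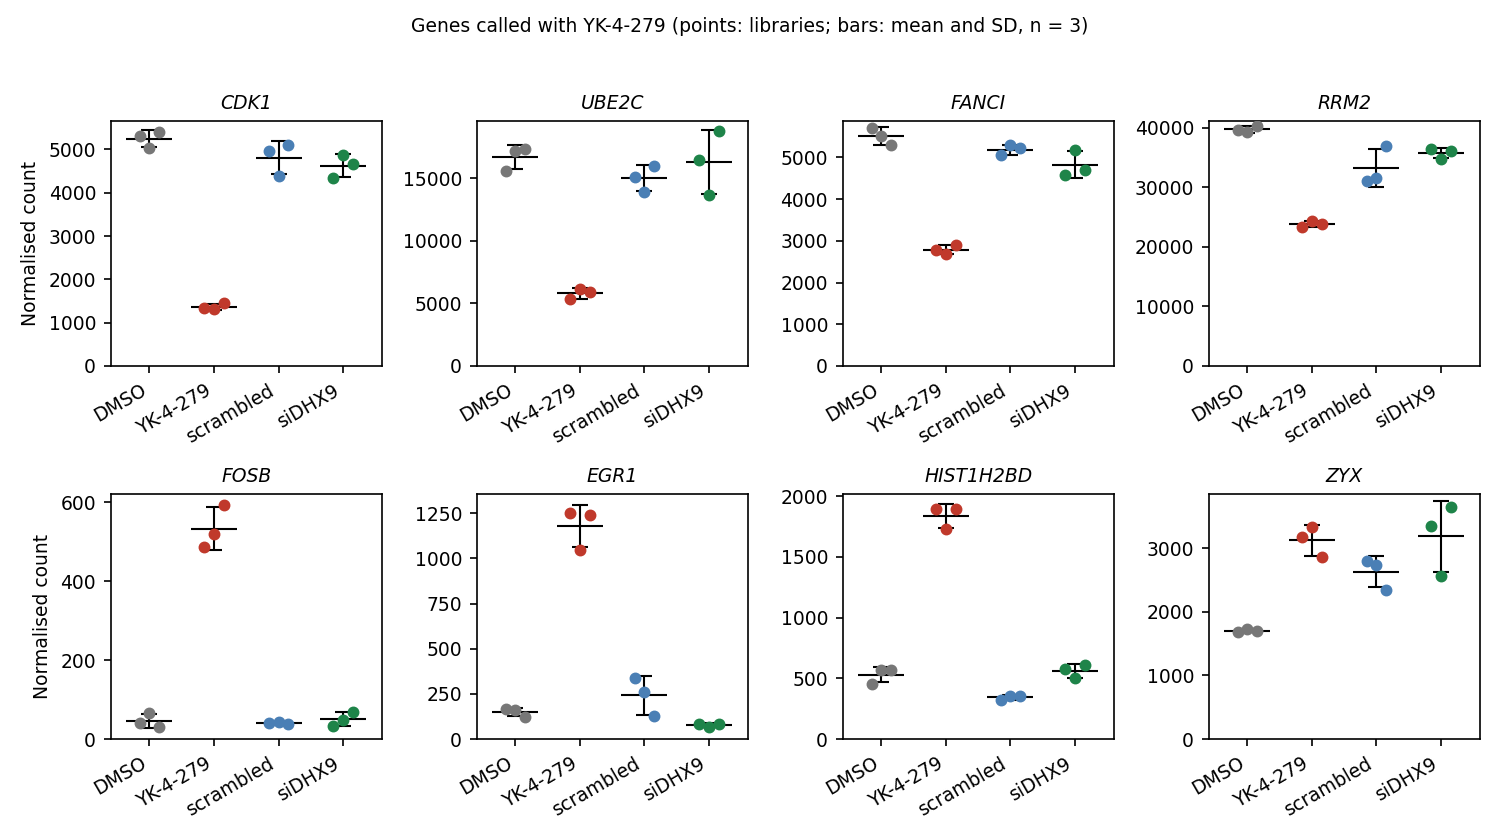
Normalised read counts of 8 genes called with YK-4-279 in each of the 4 groups. Points are libraries and bars are mean and SD (n = 3); the 3 YK-4-279 libraries lie apart from the 3 DMSO libraries in each panel, lower for CDK1, UBE2C, FANCI and RRM2 and higher for FOSB, EGR1, HIST1H2BD and ZYX.

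The second comparison asked what lower DHX9 changed, against the scrambled control. In a list of 12 neuronal genes 5 rose, and in a list of 28 genes of the integrated stress response 16 fell, or 8 without scrambled replicate 1 or 2 (adjusted p = 0.484 for each list with an estimated correlation). SYP, synaptophysin of synaptic vesicles (GSHG0032093, chromosome X), rose 7.84-fold, from 30.67 ± 0.825 to 249 ± 36.7 normalised counts (SD, n = 3, adjusted p = 1.15e-06), beside 95.02 ± 28.7 in DMSO. AP3B2, a neuronal vesicle adaptor (GSHG0010666, chromosome 15), rose 5.92-fold, from 69.45 ± 7.26 to 416.1 ± 47.1 (adjusted p = 1.55e-07), beside 209.1 ± 5.07 in DMSO. PSMD10, a proteasome assembly chaperone (GSHG0032264, chromosome X), fell 2.65-fold, from 4326 ± 384 to 1636 ± 168 (adjusted p = 3.52e-07), beside 4701 ± 113 in DMSO.

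In the list of neuronal differentiation, 5 of 12 measured members rose, or 5 rose and 1 fell adjusted over the list alone (median log2 0.24, mean 0.69, camera adjusted p = 0.0144, adjusted p = 0.484 with an estimated correlation). NEFM, a neurofilament, rose 2.31-fold to 2118 ± 270, and NEFL, another, rose 1.22-fold, with an adjusted p of 0.061 without siDHX9 replicate 1. CHGA, a granin of secretory granules, was at 68.28 ± 34.6 against 6.933 ± 6.02. The list's mean was 0.61 above DMSO in siDHX9 libraries, and in scrambled libraries it was 0.07 below with a median 0.28 above. Without scrambled replicate 3 its adjusted p was 0.0581. Other genes among the largest rises were CHRNB2 (11-fold), CHGB (8.97-fold), a further granin, NSG2 (4.3-fold), a protein of neuronal vesicles, BSN (4.08-fold), a scaffold of presynaptic zones, GNG4 (3.58-fold), a G protein subunit, and DISP2 (4.06-fold). TMEM145 rose 9.26-fold and ACTG2, a smooth muscle actin, 11.6-fold. For 9 of these 10 largest rises the scrambled mean lay below the DMSO mean, and for all 10 the siDHX9 mean lay above the DMSO mean. Choosing the largest rises over scrambled itself favours low scrambled and high siDHX9 values, so these counts only describe the genes.

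Genes of the ATF4 integrated stress response, which answers shortage of amino acids, fell in 16 of 28 measured members, or 22 fell and 1 rose adjusted over the list alone (mean log2 −0.77, camera adjusted p = 1.84e-09, adjusted p = 0.484 with an estimated correlation). PSAT1, an enzyme of serine synthesis, fell 1.6-fold to 4805 ± 396. SLC7A5, an amino acid transporter, fell 1.9-fold from 1995 ± 455, and STC2, a secreted glycoprotein, fell 2.94-fold to 248.4 ± 26.7. MTHFD2, a mitochondrial enzyme of folate metabolism, fell 1.56-fold and overlaps the entry that joins SLC4A5 and DCTN1. The number of members that fell was 8 without scrambled replicate 1, 8 without scrambled replicate 2 and 24 without scrambled replicate 3, and without scrambled replicates 1 and 2 together the list's adjusted p was 0.0357. Its mean lay above DMSO by 1.13 in scrambled and by 0.35 in siDHX9 libraries, and by 1.54, 1.36 and 0.49 in scrambled replicates 1, 2 and 3. CHAC1, which degrades glutathione, was at 4694 ± 3810 in scrambled and 425.5 ± 232 in siDHX9 libraries, a fall with an adjusted p of 0.0564 without scrambled replicate 1 and 0.0534 without scrambled replicate 2. INHBE, a subunit of activin E, had 394 reads over the 3 scrambled libraries, 2 in siDHX9 and 7 in DMSO.

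**Figure D3:**
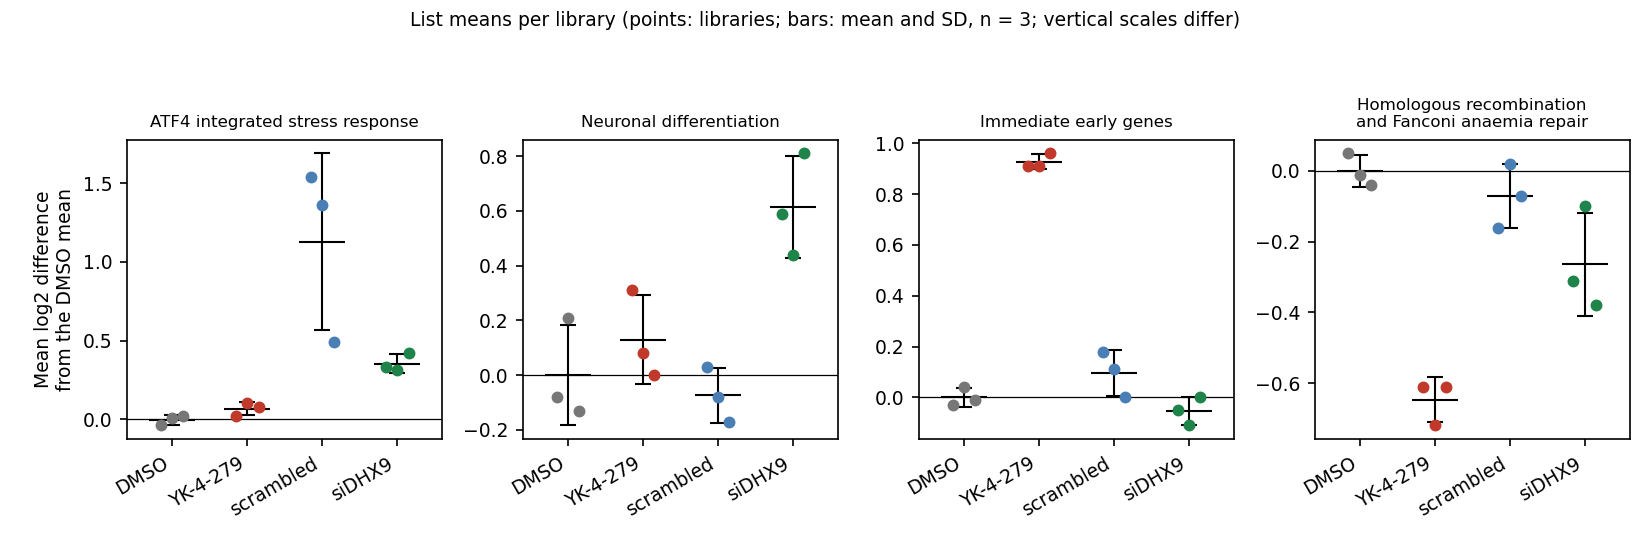
Mean log2 difference from the DMSO mean over the members of 4 gene lists in each library. Points are libraries and bars are mean and SD (n = 3), with a vertical scale of its own in each panel; scrambled replicates 1 and 2 stand at 1.54 and 1.36 in the panel of the integrated stress response.

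Enzymes of cholesterol synthesis fell in 6 of 24 members, with 6 adjusted over the list alone (mean log2 −0.20, camera adjusted p = 0.00118, adjusted p = 0.168 with an estimated correlation), and lay above DMSO by 0.52 in scrambled and 0.32 in siDHX9 libraries. HMGCS1, which makes a precursor of mevalonate, fell 1.69-fold to 6178 ± 1090, EBP, a sterol isomerase, fell 1.39-fold, and FDFT1, squalene synthase, fell 1.26-fold. Enzymes of fatty acid synthesis fell in 4 of 13, or 6 adjusted over the list alone (mean log2 −0.28, camera adjusted p = 0.0117, adjusted p = 0.484 with an estimated correlation), and lay above DMSO by 0.61 in scrambled and 0.34 in siDHX9 libraries. ACACA, acetyl-CoA carboxylase, fell 1.76-fold to 392.5 ± 65.8. Without scrambled replicates 1 and 2 together the adjusted p of fatty acid synthesis was 0.151.

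Ribosomal protein genes rose in 16 of 33 members, or 28 adjusted over the list alone (mean log2 0.26, camera adjusted p = 6.34e-10, adjusted p = 0.53 with an estimated correlation), with means against DMSO of −0.20 in scrambled and 0.06 in siDHX9 libraries. RPL37 rose 1.29-fold, RPS4X 1.25-fold and RPL7 1.21-fold, with adjusted p values of 0.0519, 0.0503 and 0.0543 without scrambled replicate 1. Host genes of small nucleolar RNAs rose in 6 of 11, or 7 adjusted over the list alone (mean log2 0.23, camera adjusted p = 0.014, adjusted p = 0.484 with an estimated correlation), with means against DMSO of −0.35 and −0.12. SNHG15 rose 1.56-fold to 1852 ± 147 and SNHG12 rose 1.48-fold. Ribosomal RNA took 2.71% ± 0.917 of reads in siDHX9 and 4.09% ± 0.964 in scrambled libraries (SD, n = 3), beside these groups. By gene span, the median log2 change in siDHX9 against scrambled ran from 0.17 in the shortest 20% of genes to −0.12 in the longest 20%, so short genes in general lay higher, and the lists were not tested against genes matched in span here.

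Genes of G2/M and mitosis fell in 7 of 28 and rose in 1, or 14 and 1 adjusted over the list alone (mean log2 −0.18, camera adjusted p = 0.000853, adjusted p = 0.202 with an estimated correlation), with a scrambled mean 0.14 above DMSO. TPX2, a spindle assembly factor, fell 1.4-fold to 16940 ± 602, KIF2C, a kinesin of chromosome attachment, fell 1.42-fold, and CCNB2, a mitotic cyclin, fell 1.37-fold. RNA helicases other than DHX9 fell in 5 of 25 and rose in 1, with the same counts adjusted over the list alone (mean log2 −0.16, camera adjusted p = 0.0202, adjusted p = 0.53 with an estimated correlation). DHX8, a splicing helicase, fell 1.35-fold to 1008 ± 39.3. The list's adjusted p was 0.0847 to 0.127 without scrambled replicate 2 or siDHX9 replicate 1. Genes of homologous recombination and Fanconi anaemia fell in 3 of 23, or 6 adjusted over the list alone (mean log2 −0.19, camera adjusted p = 0.017, adjusted p = 0.608 with an estimated correlation), with an adjusted p of 0.062 to 0.0977 without scrambled replicate 3, siDHX9 replicate 1 or siDHX9 replicate 3. By fry neither this list (adjusted p = 0.0951) nor the helicases (0.0812) passed, and the repair genes have a median span of 79.1 kb, where genes in general lay lower (median log2 −0.10 and −0.12 in the longest 2 of 5 parts).

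Among genes outside the called lists, the interferon-induced ISG15 rose 1.84-fold to 3464 ± 745 in a list of 24 with 2 higher, and 2 adjusted over the list alone (camera adjusted p = 0.209). Against DMSO, ISG15 had a log2 change of −0.49 in scrambled (limma adjusted p = 0.0174) and 0.39 in siDHX9 libraries (limma adjusted p = 0.0501). Of 33 genes activated by EWS-FLI1, 6 rose and 2 fell, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.0613), with BCL11B, a transcription factor, up 1.73-fold, PPP1R1A, a phosphatase inhibitor that overlaps PDE1B, up 1.68-fold, and NR0B1 up 1.23-fold. Against DMSO that list had a mean log2 of −0.15 in scrambled and −0.01 in siDHX9 libraries. MYC rose 1.35-fold to 30590 ± 3760. CCND1 (log2 0.08 ± 0.09), CDKN1A (0.21 ± 0.17), EWSR1 (−0.01 ± 0.08) and FLI1 (−0.04 ± 0.22) did not pass the test. The fibroblast markers THY1 and DCN rose 1.52-fold and 2.05-fold, to 519.8 ± 44 and 510.7 ± 118, in a list of 7 with 3 higher, or 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0613).

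The remaining large falls were MAP1B (3.03-fold), a microtubule-associated protein of neurons that fell from 7639 ± 461 to 2529 ± 324, EGR1 (2.9-fold, with 338.1, 262.6 and 126.7 in scrambled replicates 1, 2 and 3 beside a DMSO mean of 149.9), KLF9 (3.23-fold), a transcription factor, NATD1 (3.07-fold), AMMECR1L (2.6-fold) and SLC4A7 (2.49-fold), a bicarbonate transporter. NATD1 had an adjusted p of 0.0524 to 0.0604 without scrambled replicate 1 or siDHX9 replicate 3, AMMECR1L 0.0514 without siDHX9 replicate 3, and SLC4A7 0.053 to 0.069 without scrambled replicate 2, siDHX9 replicate 1 or siDHX9 replicate 3. For 9 of the 10 largest falls the scrambled mean lay above the DMSO mean, and for 6 the siDHX9 mean lay below it. Choosing the largest falls likewise favours high scrambled and low siDHX9 values.

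Across the 14225 genes, 1244 were higher and 1134 lower in siDHX9 than in scrambled libraries, 2378 in all, of which 367 changed by a log2 fold change of at least 1. The changes of all genes correlated inversely with those of scrambled against DMSO (Pearson r = −0.54). Their covariance was −0.1192, against −0.033 expected from the shared scrambled libraries alone. Departures of the scrambled libraries from DMSO therefore enter many of these changes, which are not all effects of lower DHX9. Of the 36 lists 9 were called by camera, against 0 with an estimated correlation and 14 by fry, and the other 27 had camera adjusted p values of 0.0613 to 0.987. Median, mean and test differed in sign for p53 targets (median −0.12, mean −0.13, test higher), aryl hydrocarbon receptor targets (−0.07, 0.09, lower), immediate early genes (0.03, −0.15, lower) and nuclear-encoded oxidative phosphorylation (0.02, −0.01, lower). The fit on the 6 libraries alone called 492 genes, of which 491 were among the 2378. That fit differs both in its spread and in having fewer residual degrees of freedom, and these were not separated. The fit on the 6 drug-arm libraries, with equally few degrees of freedom, called more genes than the main fit (4270 against 1965). The main fit takes its spread from both arms, and the drug arm was tighter. Without 1 library the count for siDHX9 against scrambled was 1255 or 1410 (scrambled replicates 1 and 2), 1301, 4255 or 1244 (siDHX9 replicates 1, 2 and 3), and it was 469 without scrambled replicates 1 and 2 together. Of the genes named above, ACACA, AMMECR1L, CHAC1, DCN, DHX8, EBP, EGR1, FDFT1, HMGCS1, INHBE, KLF9, MTHFD2, MYC, NATD1, NEFL, NR0B1, PSAT1, RPL37, RPL7, RPS4X, SLC4A7, SLC7A5, SNHG12, SNHG15, STC2 and THY1 were not called without that pair. Those of them not called on the 6 libraries alone were AMMECR1L, CHAC1, DHX8, FDFT1, MTHFD2, MYC, NEFL, NR0B1, PSAT1, RPL37, RPL7, RPS4X, SLC4A7 and SNHG12.

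**Figure D4:**
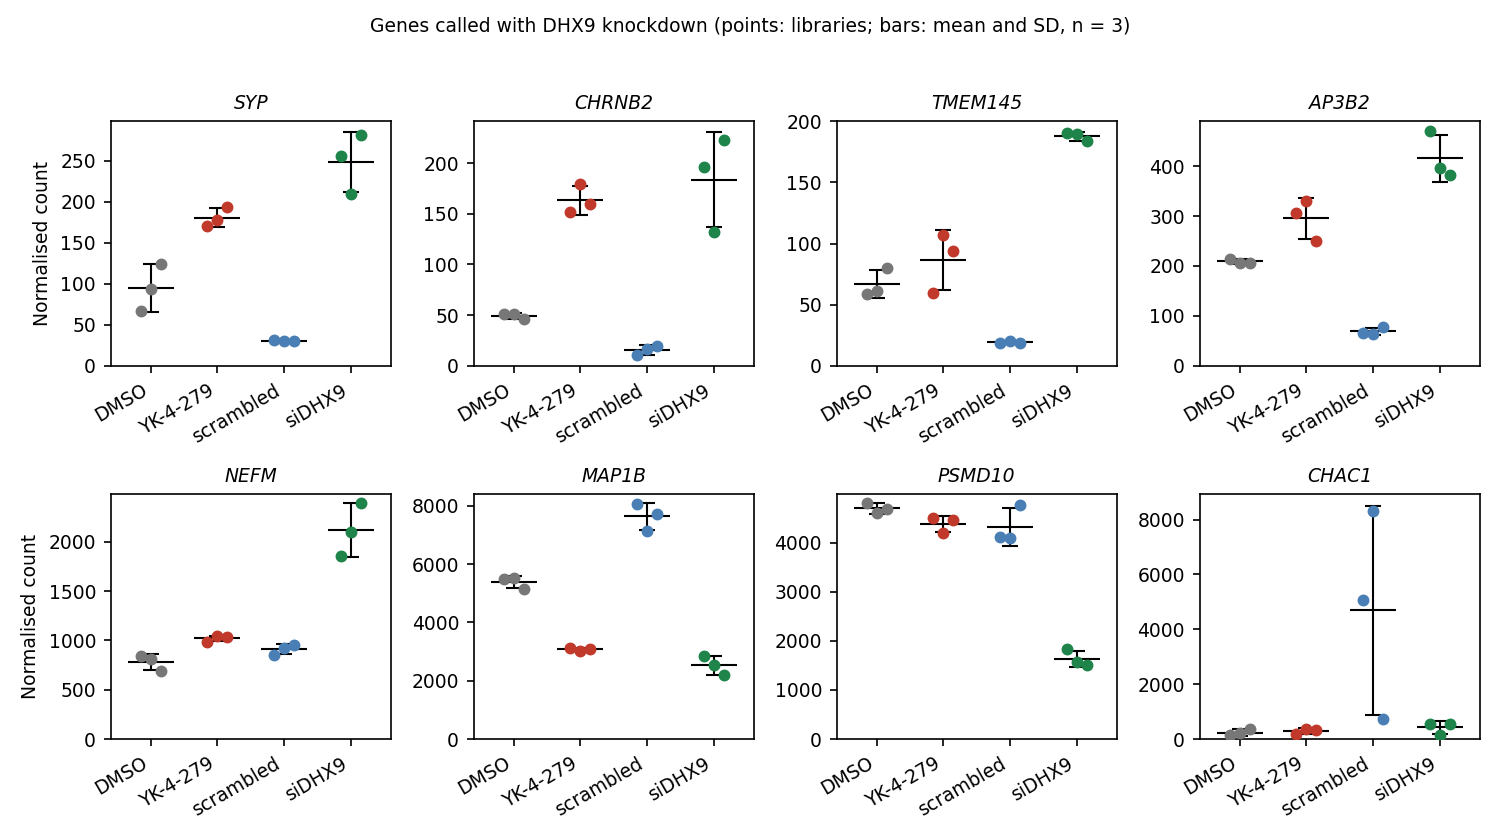
Normalised read counts of 8 genes called with DHX9 knockdown in each of the 4 groups. Points are libraries and bars are mean and SD (n = 3); for SYP, CHRNB2, TMEM145 and AP3B2 the scrambled libraries lie below DMSO and the siDHX9 libraries above it, and for CHAC1 scrambled replicates 1 and 2 stand far above the rest.

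The final comparisons asked how far the drug and the lower DHX9 changed the same genes. Genes called in both more often moved the same way. CHRNB2 and SYP rose in both (3.24-fold and 1.95-fold with YK-4-279), as did SERPINI1, neuroserpin, by 1.9-fold and 1.88-fold. MAP1B fell 1.75-fold with YK-4-279 and 3.03-fold with lower DHX9, and MAP3K1, a kinase of stress signalling, fell 1.82-fold and 2.04-fold. Further genes that rose in both were DISP2 and ARC, a synaptic protein, and further genes that fell in both were RBBP9, which overlaps POLR3F, ZMYM1 and GOLGA8H.

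Of 418 genes called in both, 299 (71.5%) moved the same way and 119 the opposite way. There were 169 genes higher in both against 91.1 expected from independent lists (odds ratio 2.18, Fisher's exact p = 5.81e-16) and 130 lower in both against 73.6 expected (odds ratio 2.01, Fisher's exact p = 8.87e-11). Genes higher with YK-4-279 and lower with siDHX9 numbered 46 against 83.1 expected (Fisher's exact p = 3.19e-06). The reverse numbered 73 against 80.7 expected (Fisher's exact p = 0.399). These tests treat genes as independent, and both lists share 1 spread from the fit on 12 libraries, so their p values are descriptive. Both comparisons also leaned the same way by gene span. From the shortest to longest of 5 parts, median log2 changes ran from 0.07 to −0.03 with YK-4-279 and 0.17 to −0.12 with siDHX9. How much of the overlap goes with span was not tested. Across the 14225 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.19 and a Spearman rho of 0.22. The 299 genes that moved the same way became 151 when each comparison was fitted on its own 6 libraries and 106 without scrambled replicates 1 and 2. That number was 113 to 163 without any 1 library of the drug arm, 158 without scrambled replicate 1, 155 without siDHX9 replicate 1 and 930 without siDHX9 replicate 2. Of the shared genes, ARC was not called with YK-4-279 without any 1 of that comparison's 6 libraries (adjusted p 0.0515 to 0.0959), DISP2 without DMSO replicate 1 or YK-4-279 replicate 2 (0.0557 to 0.0603), and RBBP9 (0.0523) and ZMYM1 (0.0635) without YK-4-279 replicate 2. With siDHX9, ZMYM1 was not called without scrambled replicate 1 (adjusted p = 0.0552) and GOLGA8H without scrambled replicates 1 or 2 or siDHX9 replicate 3 (0.0558 to 0.0979), and these 2 genes, ARC and RBBP9 were not called without scrambled replicates 1 and 2 together. On the 6 libraries of the siDHX9 comparison alone ARC, ZMYM1 and GOLGA8H were not called there either. GOLGA8H also lost that call without the mean-variance trend.

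The effects differed for 1379 genes, 626 with the higher value for YK-4-279 and 753 with the higher value for siDHX9. EGR1 rose with the drug and fell with lower DHX9, a difference of 4.51 ± 0.38 on the log2 scale (adjusted p = 4.07e-05). FOSB differed by 3.37 ± 0.41 (adjusted p = 0.000299) and ATF3, a stress-induced transcription factor, by 3.35 ± 0.71 (adjusted p = 0.0109), a call lost without scrambled replicates 1 and 2 together. AP3B2 (−2.07 ± 0.20), TMEM145 (−2.87 ± 0.32), KCNK3 (−2.23 ± 0.44), a potassium channel, and RIBC2 (−2.13 ± 0.22) had the higher value for siDHX9. KCNK3 was at 94 to 115.6 in DMSO, 12.62 to 24.04 in scrambled and 73.18 to 97.27 in siDHX9 libraries, so its difference rests on low scrambled values. For AP3B2, TMEM145 and RIBC2 all siDHX9 libraries lay above all DMSO libraries. CHGB (−2.24 ± 0.57) had an adjusted p of 0.0534 to 0.0678 without DMSO replicates 1 or 3, YK-4-279 replicate 1 or siDHX9 replicate 1. CHAC1 (3.46 ± 1.02) lost its call without any 1 library but scrambled replicate 3 and siDHX9 replicate 3 (adjusted p 0.0573 to 0.111), and so did INHBE, at few reads, without any of 6 libraries (adjusted p 0.0658 to 0.0977): DMSO replicate 2, YK-4-279 replicates 2 and 3, scrambled replicates 1 and 2 and siDHX9 replicate 1.

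The difference was also tested by list. Immediate early genes lay higher with YK-4-279 than with siDHX9 in 10 of 20 members, and 10 adjusted over the list alone (mean 1.08, camera adjusted p = 8.83e-06, adjusted p = 0.0264 with an estimated correlation), the 1 list of the 8 called to hold with that correlation. Host genes of small nucleolar RNAs lay lower in 8 of 11, and 8 adjusted over the list alone (camera adjusted p = 4.87e-06, adjusted p = 0.263 with an estimated correlation). G1/S genes lay lower in 16 of 32, or 20 adjusted over the list alone (camera adjusted p = 8.17e-12, adjusted p = 0.237 with an estimated correlation), and homologous recombination and Fanconi anaemia genes in 10 of 23, or 16 adjusted over the list alone (camera adjusted p = 6.82e-10, adjusted p = 0.302 with an estimated correlation). Integrated stress response genes lay higher in 7 of 28, or 16 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.74e-07, adjusted p = 0.68 with an estimated correlation, and 0.109 without scrambled replicates 1 and 2 together). Genes activated by EWS-FLI1 lay lower in 9 of 33 and higher in 1, or 12 and 3 adjusted over the list alone (mean −0.17, camera adjusted p = 0.0093, adjusted p = 0.237 with an estimated correlation). Against DMSO this list had a mean of −0.15 in scrambled libraries, with 10 lower and 2 higher (camera adjusted p = 0.011, adjusted p = 0.256 with an estimated correlation). In siDHX9 libraries its mean against DMSO was −0.01, with 6 lower and 6 higher (camera adjusted p = 0.632). Low scrambled values therefore enter its difference.

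Actin, SRF and YAP targets lay higher in 3 of 18, or 8 adjusted over the list alone (camera adjusted p = 0.0246, adjusted p = 0.622 with an estimated correlation), with an adjusted p of 0.0669 to 0.0785 without scrambled replicate 2 or siDHX9 replicate 2, 0.356 without scrambled replicates 1 and 2 together and 0.1 by fry. Ribosomal proteins lay lower as a list (mean −0.15, camera adjusted p = 0.00197, adjusted p = 0.816 with an estimated correlation), with an adjusted p of 0.218 without siDHX9 replicate 3, 0.0518 without scrambled replicates 1 and 2 together and 0.363 by fry, a call also lost under quantile normalisation, and with 0 of 33 members called by limma, also adjusted over the list alone, against 6 at an unadjusted p under 0.05, 3 by edgeR and 2 by DESeq2. Median, mean and test differed in sign for NF-kB targets (median 0.05, mean −0.08, test lower), WNT targets (0.14, 0.22, lower), epithelial markers (−0.08, −0.14, higher), the circadian clock (−0.02, 0.06, higher) and leukocyte and blood markers (0, 0.05, lower). The arms also differ in delivery and in hours, so the difference compares the experiments as run. It was 440 genes without scrambled replicates 1 and 2, and 762, 836, 790, 833, 875 and 919 without DMSO replicate 2, DMSO replicate 3, YK-4-279 replicate 1, YK-4-279 replicate 3, scrambled replicate 1 and siDHX9 replicate 1.

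**Figure D5:**
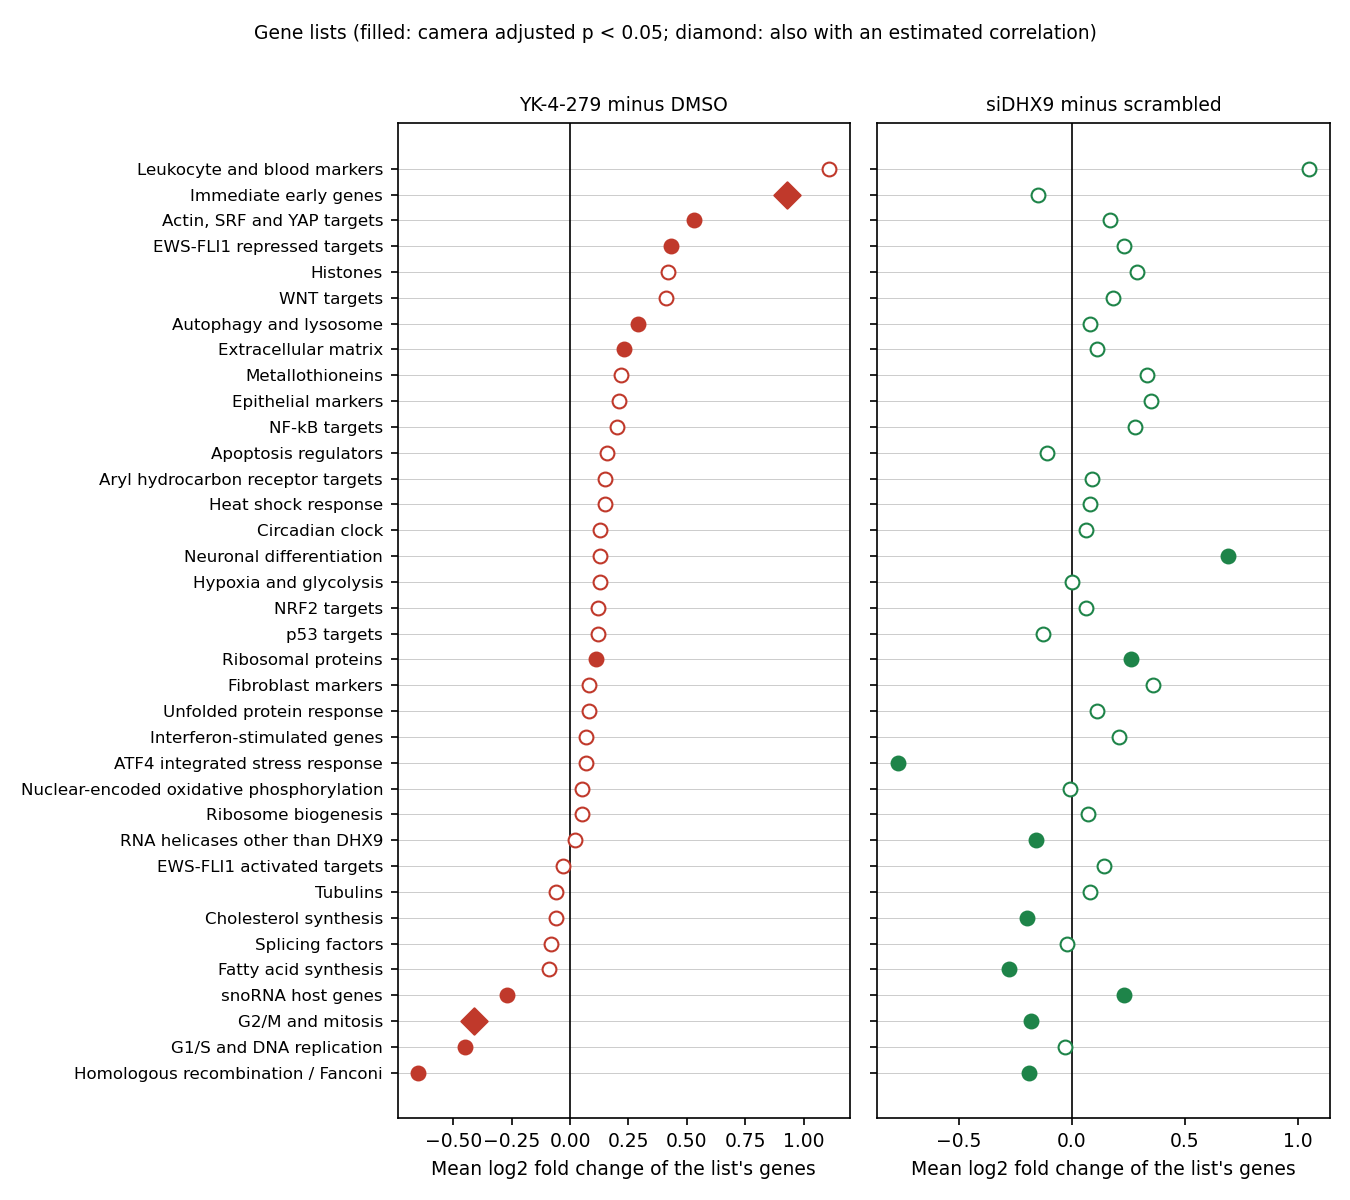
Mean log2 fold change of each tested gene list with YK-4-279 and with siDHX9, on a horizontal scale of its own in each panel. Filled points had a camera adjusted p under 0.05, and diamonds, for immediate early genes and for G2/M and mitosis with YK-4-279, held with an estimated correlation.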

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

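The test of the difference, its test by list, the scalings and the leaving out of single libraries were planned, and the reading of the gene span test was written down before it was run. The splits of the libraries, the comparison with DMSO, the fit without scrambled replicates 1 and 2 together, the use of scaling and of single libraries as tests of an explanation, and the tests of entries without a symbol were chosen only after the results were seen.

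The difference between the effects of YK-4-279 and of lower DHX9 was tested directly, and 1379 genes passed at an adjusted p under 0.05. Among 100 splits of the libraries in each arm, 4 gave at least as many genes, and the highest other split gave 3241. That split kept the drug arm as labelled and swapped the siRNA arm, and the splits with 1887 and 1831 genes also kept the drug arm, so these splits carry the drug effect and are not free of signal. For YK-4-279 the labelled split gave 1965 genes and the highest of the other splits 1, so that 1 of 10 splits reached the labelled count. For lower DHX9 the labelled split gave 2378 genes and the highest of the others 0, again 1 of 10. With 10 splits there are too few for a share under 0.05.

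The same test by list passed for 8 lists (camera), of which only immediate early genes held with an estimated correlation (adjusted p = 0.0264, against 0.237 to 0.816 for the other 7). The lists with the higher value for YK-4-279 were immediate early genes such as EGR1 and FOSB (adjusted p = 8.83e-06), the integrated stress response (adjusted p = 4.74e-07, but 0.109 by fry and 0.109 without scrambled replicates 1 and 2 together), and actin, SRF and YAP targets (adjusted p = 0.0246, but 0.1 by fry). The lists with the lower value for YK-4-279 were G1/S and DNA replication (adjusted p = 8.17e-12), homologous recombination and Fanconi anaemia repair (adjusted p = 6.82e-10), host genes of small nucleolar RNAs (adjusted p = 4.87e-06), ribosomal proteins (adjusted p = 0.00197, but 0.363 by fry) and genes activated by EWS-FLI1 (adjusted p = 0.0093). Against DMSO, genes activated by EWS-FLI1 had a mean log2 of −0.15 in scrambled and −0.01 in siDHX9 libraries, so low scrambled values enter their difference.

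Entries without a gene symbol were outside the tests, and signals appeared there as well. With YK-4-279, 344 of 3172 such entries changed, of which 286 (83.1%) were lower, and with lower DHX9 315 changed, 169 higher and 146 lower.

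Genes of the integrated stress response, among them PSAT1, SLC7A5 and CHAC1, were lower in siDHX9 than in scrambled libraries. A stress response raised in the scrambled libraries could account for this, since the list's mean lay 1.13 above DMSO in scrambled and still 0.35 above DMSO in siDHX9 libraries. No single scrambled library made the whole pattern, as the largest camera adjusted p without any 1 of them was 1.39e-06 (the list's adjusted p with an estimated correlation and all libraries was 0.484), but the members called lower dropped from 16 to 8 without scrambled replicate 1 or 2. The deposited scaling was not the source either, with a smallest mean change of −0.79 under TMM or quantile scaling. An effect of DHX9 itself on this response stays open, because no transfected group with another control was measured.

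Genes of replication and repair, among them CDC45, RRM2, BLM and FANCI, were lower with YK-4-279, although both lists had an adjusted p of 0.0736 with an estimated correlation. Long genes lose reads first when transcription slows, which might lower a list of long genes. The median span was 79.1 kb for the repair list and 20.4 kb for the G1/S list, against 29.8 kb for all genes. The test therefore bears on the repair list only. For each list, 0% of 10000 random lists matched in span and level had a median as low. Random lists lack members that move together, so this share is not a p value. The lowest random medians were −0.24 and −0.17, against −0.7 for homologous recombination and Fanconi anaemia repair and −0.47 for G1/S genes. Scaling did not account for it, as the smallest mean change of the lists under TMM or quantile scaling was −0.46. An effect of YK-4-279 on these genes or on the cell cycle stays open and was not tested further here.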

How the results depend on the processing

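The fit shares 1 spread over 12 libraries, and the drug arm was tighter than the siRNA arm, while a fit on 6 samples also has fewer residual degrees of freedom, and these were not separated. Where no reason is given, the cause was not tested. Values of lists are camera adjusted p values, and those below changed direction without being called.

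On its own 6 samples YK-4-279 changed 4270 genes (2325 higher, 1945 lower) and lower DHX9 492 (294 higher, 198 lower), with 151 called in both in the same direction and 47 in opposite directions; p53 targets (0.901) and oxidative phosphorylation (0.955) reversed for lower DHX9. DHX9 with YK-4-279 passed at −0.21 in that fit (adjusted p = 0.0038), at −0.24 with TMM (0.0241), −0.25 with quantile normalisation (0.0279), −0.24 in edgeR (0.0246), −0.23 in DESeq2 (0.0161) and −0.21 with array weights (0.00446).

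DESeq2 gave 2081 genes whose effects differ (968 higher), 495 in both in the same direction and 184 opposite, and p53 targets reversed for lower DHX9 (0.993). With a log2 fold change of at least 1, YK-4-279 changed 205 genes (132 higher, 73 lower), lower DHX9 367 (250 higher, 117 lower) and the difference 390 (172 higher, 218 lower), with 21 in the same direction and 4 opposite. Camera with an estimated correlation called 2 lists for YK-4-279, 0 for lower DHX9 and 1 for the difference, and fry called 14 for lower DHX9.

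Array weights gave 4664 genes for YK-4-279 (2530 higher, 2134 lower), 4267 for lower DHX9 (2188 higher, 2079 lower) and 3477 for the difference (1754 higher, 1723 lower), with 1118 in the same direction and 416 opposite; FLI1 (log2 0.22), oxidative phosphorylation (0.959) and epithelial markers (0.859) reversed for lower DHX9. Without both scrambled replicates 1 and 2, lower DHX9 changed 469 genes (265 higher, 204 lower) and 16 lists, and the difference 440 (150 higher, 290 lower), with 106 in the same direction and 20 opposite; heat shock (0.388), ribosome biogenesis (0.756) and the circadian clock (0.885) reversed for lower DHX9.

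A mean of at least 50 reversed interferon-stimulated genes with YK-4-279 (0.904) and oxidative phosphorylation with lower DHX9 (0.844), which also reversed with unnamed entries included (0.981). Ribosome biogenesis with YK-4-279 reversed under TMM (0.907) and quantile normalisation (0.927), and the latter reversed FLI1 (log2 0.01), hypoxia and glycolysis (0.847) and tubulins (0.809) for lower DHX9. The replicate block gave 77 opposite genes and reversed oxidative phosphorylation for lower DHX9 (0.977). Equal numbers had r values of 0.12, 0.05 and −0.01 in the drug arm and 0.05, 0.06 and 0.08 in the siRNA arm. Each siRNA-arm library correlated best with its own number. Such low values give little sign of pairing but cannot exclude it, and the main fit used none.

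Leaving out each library in turn gave 858 to 2795 genes for YK-4-279 (376 to 1593 higher, 482 to 1233 lower), 1244 to 4255 for lower DHX9 (657 to 2284 higher, 580 to 1971 lower) and 762 to 1883 for the difference (315 to 917 higher, 436 to 1008 lower), with 113 to 930 in the same direction and 45 to 179 opposite. Lists called were 8 to 10 for YK-4-279, 7 to 15 for lower DHX9 and 7 to 9 for the difference. DHX9 with YK-4-279 ranged from −0.24 to −0.18, and passed without scrambled replicate 3, siDHX9 replicate 2 or siDHX9 replicate 3. Reversed in some of these fits with YK-4-279 were interferon-stimulated genes (0.713 to 0.994), RNA helicases other than DHX9 (0.523 to 0.924) and ribosome biogenesis (0.691 to 0.998). With lower DHX9 they were oxidative phosphorylation (0.291 to 1), circadian clock (0.476 to 0.946), p53 targets (0.71 to 1), epithelial markers (0.49 to 0.959), G1/S (0.166 to 0.927), splicing factors (0.399 to 0.927), NRF2 targets (0.242 to 0.992), tubulins (0.171 to 0.947), EWSR1 (log2 −0.11 to 0.05) and FLI1 (−0.27 to 0.17).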

Other observations

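The comparisons with DMSO, the REST target list and the search for seed matches were tests chosen only after the results were seen, although the reading of the REST test was written down before its list was tested. The comparisons with DMSO were added late, and they mix transfection with the hours of culture. In scrambled libraries, cholesterol synthesis genes rose in 19 of 24 members against DMSO, with 19 adjusted over the list alone (mean log2 0.52, camera adjusted p = 9.18e-13, adjusted p = 0.00216 with an estimated correlation). In siDHX9 libraries 11 rose, or 13 adjusted over the list alone (mean log2 0.32, camera adjusted p = 7.57e-06, adjusted p = 0.0319 with an estimated correlation). HMGCS1 was higher than in DMSO by a log2 of 1 in scrambled libraries (adjusted p = 0.000485) and by 0.25 in siDHX9 libraries (adjusted p = 0.252).

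Extracellular matrix genes rose in 9 of 21 members in siDHX9 against DMSO, or 13 adjusted over the list alone (mean log2 0.41, camera adjusted p = 8.56e-05, adjusted p = 0.151 with an estimated correlation). In scrambled libraries 8 rose and 1 fell, or 10 and 1 adjusted over the list alone (mean log2 0.30, camera adjusted p = 0.00963, adjusted p = 0.358 with an estimated correlation), and siDHX9 against scrambled had a camera adjusted p of 0.334. In siDHX9 libraries fibroblast markers rose in 6 of 7, and 6 adjusted over the list alone (mean log2 0.68, camera adjusted p = 0.000202, adjusted p = 0.135 with an estimated correlation), and in scrambled libraries 2 rose, or 3 adjusted over the list alone (mean log2 0.32, camera adjusted p = 0.105). THY1 was higher than in DMSO by 0.92 in siDHX9 libraries (adjusted p = 0.000154) and by 0.32 in scrambled libraries (adjusted p = 0.0585), and DCN by 0.87 in siDHX9 libraries (adjusted p = 0.0127).

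Neuronal genes such as SYP, CHGB and NEFM were higher in siDHX9 than in scrambled libraries, but for SYP (DMSO 95.02, scrambled 30.67, siDHX9 249) and CHGB (49.29, 14.19 and 113.2) more than 50% of the log2 rise came from scrambled libraries lying below DMSO. In the neuronal list 5 of 12 members rose (camera adjusted p = 0.0144, adjusted p = 0.484 with an estimated correlation). The list as a whole lay 0.61 above DMSO in siDHX9 libraries (median 0.37, camera adjusted p = 0.000112, adjusted p = 0.135 with an estimated correlation). In scrambled libraries its mean lay 0.07 below DMSO and its median 0.28 above. A low scrambled baseline was thus not seen for the list as a whole. These comparisons mix transfection with hours of culture and cannot exclude it. For REST, a repressor of neuronal genes that was lower in siDHX9 than in scrambled libraries (log2 −0.77, limma adjusted p = 0.00711) and than in DMSO (−0.84, limma adjusted p = 0.00372), 11 of 20 measured targets rose against scrambled (mean 0.79, limma's camera on 1 list, so that the adjusted p is the p itself, adjusted p = 4.67e-08), but most of that was scrambled lying 0.65 below DMSO at a REST level 0.07 below DMSO, siDHX9 lay only 0.13 above DMSO (adjusted p = 0.0774), and the targets also lay higher with YK-4-279 (mean 0.37, adjusted p = 0.00642), where REST differed by −0.07 (adjusted p = 0.814). For seed matches of either reagent, the lowest 7-base word in 3' untranslated regions had a z of −6.9 against −5.3 over 100 shuffles. The same word had −7.4 in siDHX9 against DMSO, which shares the siDHX9 libraries. It had 0 sites in REST, while the next lowest words, ACTTCTA and CACTTCT, had 2 sites each there. These words overlap in sequence, so their sites may be the same. The highest word, at 6.5, was also the lowest in scrambled against DMSO, at −6.6. Those comparisons share the scrambled libraries with opposite sign, so the values are not separate evidence. With YK-4-279, without an siRNA, the lowest word had a z of −7.6. Lower REST and seed matches stay open beside an untested effect of DHX9 itself, since the REST targets were chosen after the gene table had been seen and the siRNA sequences are not given in the sources used here.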
